A study of Mytilus galloprovincialis and Mytilus trossulus with 36 samples.

How the data were processed

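Gill RNA of 36 mussels was measured on 36 Agilent 2-colour arrays, with 6 mussels in each of 6 groups. The groups were M. galloprovincialis and M. trossulus sampled at the start (zero-time control), after 4 h at 1000 mOsm/kg (4 h control) and after 4 h at 850 mOsm/kg. Per the labels, each array carried the RNA of 1 mussel in the red channel and a reference pool of the same species in the green channel, and no dyes were swapped. All ratios here are red over green, so a positive value means more signal in the mussel than in its species' pool. Each species had its own pool and its own mismatches to the probes, so levels were compared between groups of 1 species and never between species.

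Per the file headers, the signals were extracted with Agilent Feature Extraction 9.5.3.1, and the mean spot signals, local background signals and processed signals are in units of intensity. The deposited log ratio of each spot is the log10 of red over green processed signal. The authors' deposited value table holds log2 ratios of red over green for 14279 probes of 7040 targets. Its scale, direction and probe names were found by setting each column against the log ratio of the same array (slopes of 1.00 to 1.03, Pearson's r of 0.982 to 0.999 across probes, with 60.6% to 85.7% of values equal within 0.001). The origin of the remaining differences and how the authors chose those probes stay unknown, and no column is centred on 0. The column medians, in the order of the replicate numbers, were -0.182, -0.0054, -0.0686, -0.0536, -0.056 and -0.0492 in M. galloprovincialis at 850 mOsm/kg. They were -0.0841, -0.0613, -0.0341, -0.0754, -0.0605 and -0.136 in its 4 h control, and -0.198, -0.0421, -0.0465, -0.0832, -0.152 and -0.0689 in its zero-time control. In M. trossulus they were -0.0898, -0.0652, -0.0808, -0.00729, -0.196 and -0.06 at 850 mOsm/kg, -0.137, -0.0914, -0.0768, -0.0929, -0.085 and -0.0651 in the 4 h control, and -0.121, -0.137, -0.0482, -0.0751, -0.106 and -0.0916 in the zero-time control.

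Mean spot signals were corrected with limma 3.58.1 (R 4.3.3, data.table version 1.17.8) by normexp with an offset of 50 on the local median background, and log2 ratios were normalised by loess within each array. Control spots had weight 0 in the loess and were then left out, and outlier spots were set to missing. Each array had 105072 spots, of which 103747 were not controls, for 44570 probes of 11812 targets. A target is an assembled transcript named in the files, with the prefix MYC for M. californianus sequences and MPC for M. galloprovincialis sequences. The labels state that only probes performing well in both species were used, without giving the rule. Here a probe was kept when, in each species, the red signal was well above background on at least 4 of 6 arrays of any group and the green signal on at least 9 of 18 arrays. This kept 6193 probes. Spots of a probe and then kept probes of a target were averaged, and a target needed values on at least 3 arrays of each group, which left 3524 targets. Of these, 1685 had more than 1 kept probe, 1382 carried a usable annotation and 1372 were annotated as having no significant hit. The 36 arrays limit the precision, with a median SE of 0.157 (log2) for effects averaged over both species and 0.223 for effects in 1 species.

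A model with 1 mean per group was fitted to all 36 arrays with lmFit, and contrasts were tested with the moderated test of limma (eBayes), 2-sided, with Benjamini-Hochberg adjustment over the 3524 targets. A target is called at an adjusted p under 0.05. The salinity effect is 850 mOsm/kg minus the 4 h control, and the time effect is the 4 h control minus the zero-time control. Both were tested averaged over the species, in each species, and as a difference between the species (interaction). Fixed lists of genes, 26 in all, were matched by annotation, and the 22 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 and, as an alternative, with an estimated correlation. Adjustment over lists was within each contrast. These choices, the lists and the rule for named genes were fixed before the data were examined.

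The rule names annotated targets and 1 target per annotation. It takes up to 15 called targets per direction of the salinity effect in both species with the same sign in each, up to 10 of the interaction (the 5 with the smallest p if fewer pass), up to 5 per direction in each species, up to 8 per direction of the time effect, and up to 4 members per list. It gave 123 targets. Of these, 54 had fewer than 6 of 6 arrays well above background in a 4 h control or low-salinity group. Salinity effects that reach background are fitted values. After values were seen, the list members were narrowed to those called in a salinity test or in a list of under 5 members, and the table of alternatives was narrowed with them, to 69 targets. This also lowered the number of reversed values to be printed. A spelling error in the pattern that removes hypothetical proteins from the annotated targets was corrected after values were seen. Targets outside the rule are said to be so where they appear.

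The procedure was tested on simulated data with the spread of the real arrays and 200 changed targets. For changes in both species it recovered 31 of 67 targets changed by 0.5 (log2), 63 of 67 changed by 1 and 65 of 66 changed by 2, with 4.22% false calls. For a change in M. galloprovincialis alone, the interaction recovered 2 of 67, 33 of 67 and 62 of 66 of these. A simulated shift of 0.4 in 1 list was called and no other list was. The simulated noise was independent between targets, so this does not test list calls where members vary together.

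The arrays were scanned on 5 days. The 850 mOsm/kg and 4 h control groups of both species share scan days 2 and 3 (2 arrays of each group per day) and day 5 (1 array of each group). Replicate 1 of M. galloprovincialis at 850 mOsm/kg and replicate 1 of the M. trossulus 4 h control were scanned on day 1. Replicate 6 of the M. galloprovincialis 4 h control and replicate 6 of M. trossulus at 850 mOsm/kg were scanned on day 4. Neither day holds both of these groups of 1 species, so a difference between days enters each species' salinity effect and the interaction. The 4 h and zero-time controls of both species share day 5, and those of M. galloprovincialis also day 4. Effects were recomputed within these days and with scan day as a block. Taken over both species, the 850 mOsm/kg and 4 h control groups have equal numbers of arrays on each day. Except where values are missing, the block therefore could not move a salinity effect averaged over both species, only its SE. Directions within a day of targets called over all days use the same arrays and are not independent of the calls. The files give no slide, so the slide was not tested as a block.

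Where a target was not well above background on any zero-time array of a species, its rise over time is given as "at least" a fold. This sets the mean red signal of the 4 h control after loess and Aquantile normalisation against the mean, per zero-time array, of the lowest signal among probes well above background or of the probe's own signal, whichever is higher. Without dye swaps these bounds are open to dye bias. The alternatives covered the background correction, the normalisation, the probe filter, the unit of test, the authors' value table, the choice of control, the authors' 2-way analysis of variance, blocks, array weights, single arrays left out and the list settings. The species main effect was left out because probe mismatches differ between the species.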

Results

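The study measured how gill transcripts of an invasive and a native blue mussel, Mytilus galloprovincialis and M. trossulus, responded to an abrupt drop in salinity. Mussels were acclimated for 4 weeks at 13 °C and 1000 mOsm/kg. Groups of 6 mussels per species were sampled at the start, after 4 h in a tank at 1000 mOsm/kg, and after 4 h in a tank at 850 mOsm/kg (measured at 979 and 858 mOsm/kg). Treated mussels and 4 h controls had their valves held open with corks. The median red signal per array ranged from 54.4 to 292.9 intensity units around a median of 59.6, and 10.1% to 48.8% of probes were well above background in red. At 850 mOsm/kg, 3 arrays (replicate 2 of M. galloprovincialis and replicates 4 and 6 of M. trossulus) had median red signals of 176.0, 292.9 and 152.8, while the other 33 arrays were at or below 78.7. The number of arrays limits the precision of every value.

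The first comparison asks which transcripts low salinity changed in both species relative to mussels that spent the same time in a tank. Mussels at different salinities cannot share a tank, and the tank was not part of the model. Differences between tanks therefore cannot be told apart from salinity, and every n counts mussels and not tanks. CCAAT/enhancer binding protein (C/EBP, MYC06119), a transcription factor of stress and inflammatory programmes, fell 3.01-fold relative to the 4 h control (log2 -1.59 ± 0.18 SE, n = 6 mussels per group and species, adjusted p = 2.5e-07), lower in 12 of 12 mussels at 850 mOsm/kg than the control mean of their species. c-Jun (MYC06621), part of the AP-1 transcription factor, had a log2 change of -1.15 ± 0.22 (adjusted p = 0.00154), and immediate early response 5-like (MYC07287) one of -0.91 ± 0.15 (adjusted p = 0.000338), each in 12 of 12 mussels. Kruppel-like factor (MYC06168), a zinc finger transcription factor, fell by 0.93 ± 0.26 in 11 of 12 mussels (adjusted p = 0.0436), a call kept in only 8 of 19 alternatives.

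Single genes of other functions fell as well, while the lists of apoptosis genes and of ion channels were not called (adjusted p = 0.27 each). Baculoviral IAP repeat-containing 3 (BIRC3, MYC12204), an inhibitor of apoptosis, fell by 1.51 ± 0.24 on the log2 scale (adjusted p = 0.000308), lower in 11 of 12 mussels. Tumor necrosis factor receptor superfamily member 19 (MYC02394) fell by 0.87 ± 0.16, LPS-induced TNF-alpha factor (MYC02904) by 0.75 ± 0.18 and cysteinyl leukotriene receptor 1 (MYC05297), a receptor for lipid mediators of inflammation, by 0.98 ± 0.20. Pannexin 2 (MYC02781) fell by 1.34 ± 0.22 (12 of 12 mussels, adjusted p = 0.000338) and pannexin 3 (MYC08299) by 0.90 ± 0.23 (11 of 12 mussels, adjusted p = 0.0257). Pannexins form large-pore channels in the cell membrane. An amino acid transporter (MYC01780) fell by 0.85 ± 0.11 in 12 of 12 mussels (adjusted p = 7.1e-06), whereas the taurine transporter (MYC10085), a carrier of a major organic osmolyte of mussels, was not called (log2 -0.10 ± 0.11, adjusted p = 0.689). At low salinity the amino acid transporter was well above background on 3 of 6 arrays of M. galloprovincialis and 5 of 6 of M. trossulus. In M. galloprovincialis its mean there (-0.29) was near that of the zero-time control (-0.30), where no array was well above background. The size of its fall is therefore a fitted value. The other named targets that fell were ubiquitin-protein ligase-like (MYC03819, by 1.24 ± 0.25), bone morphogenetic protein 2/4 (MYC13283, by 0.80 ± 0.15), sterile alpha motif domain-containing protein 7 (MYC05755, by 0.72 ± 0.18) and GTP-binding protein SB128 (MYC02740, by 0.72 ± 0.21), with adjusted p of 0.00314, 0.0015, 0.0175 and 0.0479. The call of GTP-binding protein SB128 was kept in only 6 of 18 alternatives.

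Among targets called for salinity over both species, 8 annotated ones rose with the same sign in each, counting 1 target per annotation. An ETS-family transcription factor (MYC00286) rose 1.91-fold (log2 0.93 ± 0.23, adjusted p = 0.0183), higher in 11 of 12 mussels, and a potassium channel (MYC00516) rose 1.66-fold (log2 0.73 ± 0.17, adjusted p = 0.014), higher in 12 of 12. Lymphoid-restricted membrane protein (MYC13087) rose by 0.70 ± 0.17 on the log2 scale in 9 of 12 mussels, and transcription elongation factor B polypeptide 3 binding protein 1 (MYC02073) by 0.65 ± 0.14 in 12 of 12. Smaller rises were those of 40S ribosomal protein S6 (MYC00152, 0.50 ± 0.13), ceramide kinase (MYC07914, 0.49 ± 0.14), complement component 1 Q subcomponent-binding protein (MYC02037, 0.42 ± 0.12) and warts (MYC00275, 0.28 ± 0.08), a kinase of the Hippo growth control pathway. Their calls were kept in only 10 of 19, 6 of 18, 8 of 19 and 7 of 19 alternatives. The strongest targets without an annotation, chosen after their values were seen, were MYC03126 (log2 -2.35, adjusted p = 2.2e-09, 12 of 12 mussels) and MYC03305 (log2 1.29, adjusted p = 0.0324, 12 of 12 mussels).

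Among the gene lists, immediate early transcription factors and stress signalling shifted lower, with 6 of 20 members called lower and none called higher. Adjusted over the list alone, 8 were lower and 1 higher. The median was -0.16 (adjusted p = 0.00055; adjusted p = 0.21 with an estimated correlation), and dual specificity protein phosphatase 3 (MYC12306), which inactivates MAP kinases, was another member that fell (log2 -0.51, adjusted p = 0.0254). Ubiquitin conjugation and ligases shifted lower (median -0.13, 2 of 20 members called lower, 3 adjusted over the list alone, adjusted p = 0.011; adjusted p = 0.39 with an estimated correlation), with ubiquitin-conjugating enzyme E2-17 kDa (MYC06364) at -0.43 (adjusted p = 0.0485), a call kept in 4 of 19 alternatives. Ribosomal proteins shifted higher (median 0.36, 1 of 7 members called higher, 4 adjusted over the list alone, adjusted p = 0.0016; adjusted p = 0.39 with an estimated correlation). In 6 of these 7 members some probes had saturated spots, and with probes never saturated the median of the 6 members left was 0.48 (adjusted p = 0.013). Other list members that fell were heat shock protein 25 (MYC13256, by 0.62), eukaryotic translation initiation factor 5 (MYC02649, by 0.63), eukaryotic initiation factor 4A (MYC05671, by 0.52), intraflagellar transport protein 52 (MYC10132, by 0.71), which serves the assembly of cilia, and myosin light chain kinase (MYC09425, by 0.59), with adjusted p of 0.0335, 0.002, 0.0471, 0.0112 and 0.0183. The calls of heat shock protein 25, eukaryotic initiation factor 4A and dual specificity protein phosphatase 3 were kept in only 9 of 19, 6 of 19 and 8 of 18 alternatives. Of the 27 members of the list of cilia genes, the transport protein was the 1 called, and the list was not (adjusted p = 0.64).

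In all, 105 of 3524 targets were called by limma, 31 higher and 74 lower, and 42 of them carried an annotation (665 targets had an unadjusted p under 0.05). The called targets kept their direction within scan day 2 in 104 of 105 cases, within day 3 in 105 of 105 and within day 5, with 1 array per group, in 92 of 105, and with scan day as a block 146 targets were called, 46 higher and 100 lower. The block cannot move these averaged effects, so its count and its list tests below do not check them for scan day. On scan days 2, 3 and 5, C/EBP (MYC06119) was at -1.59, -1.63 and -1.51 and BIRC3 (MYC12204) at -1.24, -1.94 and -0.71. The median of the immediate early list was -0.10, -0.29 and 0.01 on these days (-0.16 with the block, adjusted p = 0.00048), that of the ubiquitin list 0.06, -0.24 and 0.10 (adjusted p = 0.0076 with the block) and that of the ribosomal list 0.24, 0.62 and 0.24 (adjusted p = 0.0026 with the block). The excess of lower calls depended on the loess, since without it 57 targets were higher and 38 lower. In the authors' value table, where 51 targets were called, the median of the immediate early list was 0.00 (adjusted p = 0.055) and the ubiquitin list was not called (adjusted p = 0.099), nor was it with the stricter filter (0.111), and scale normalisation, with 29 calls, ended the call of the ribosomal list (adjusted p = 0.06).

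**Figure D1:**
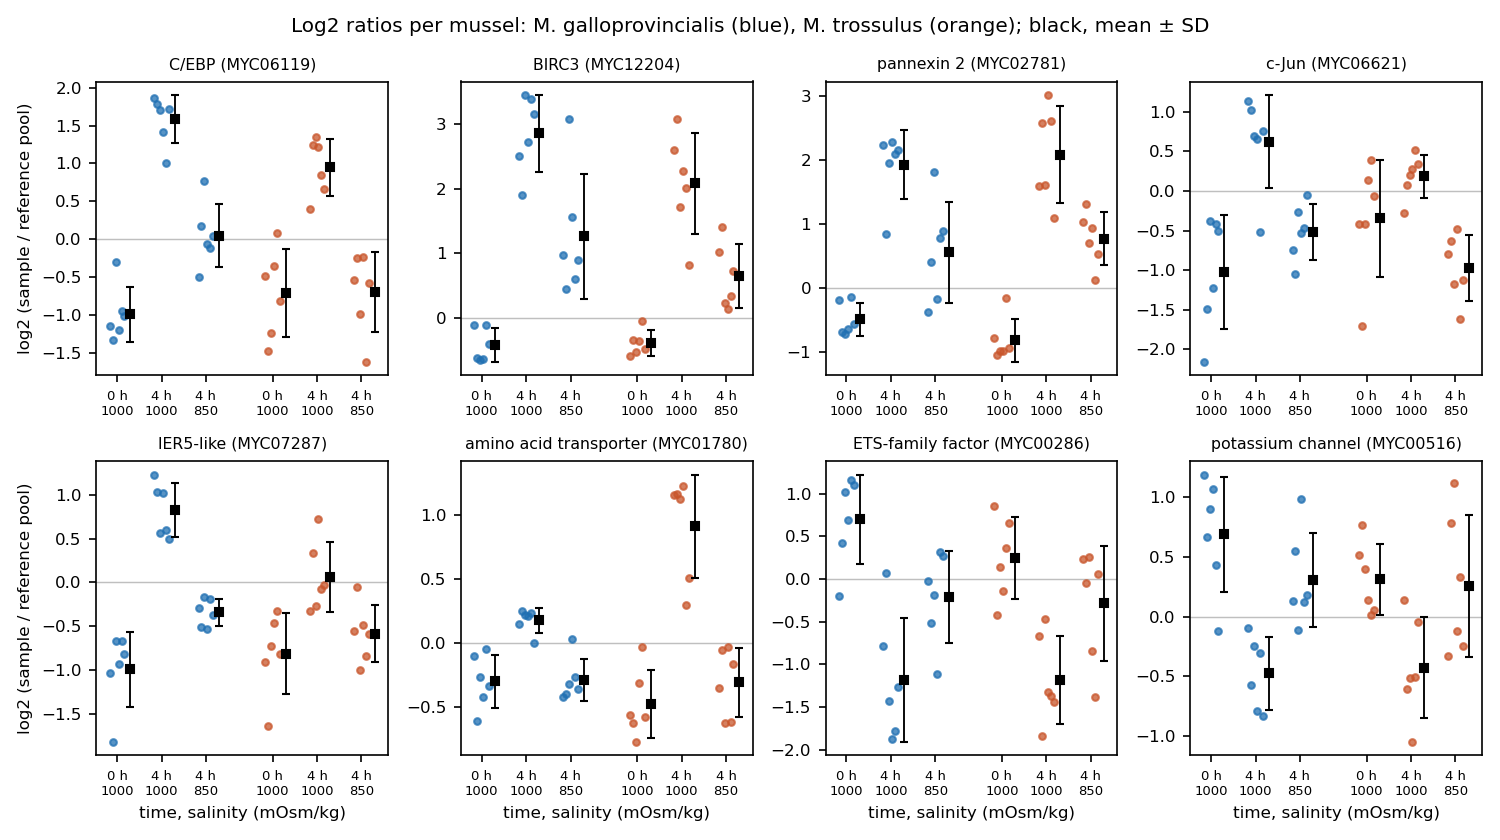
Log2 ratios of gill signal over the species' reference pool for 8 targets, 1 point per mussel, with black squares and bars for the mean and SD of 6 mussels. The mean of C/EBP at 850 mOsm/kg lies 1.53 below the 4 h control in M. galloprovincialis (blue) and 1.65 below it in M. trossulus (orange).

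**Figure D2:**
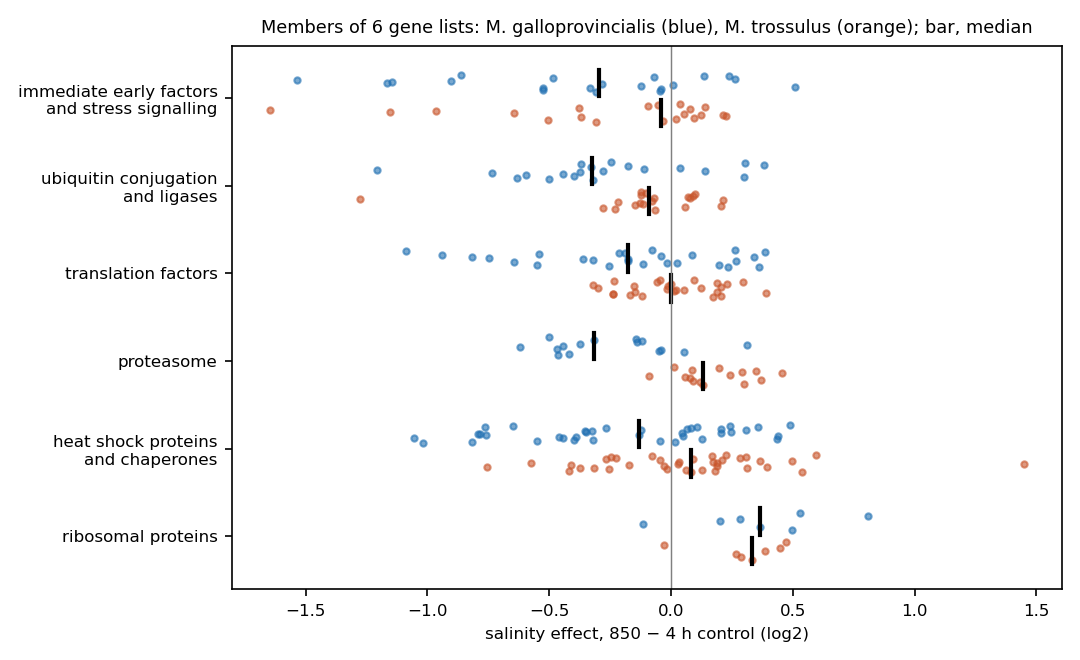
Salinity effect (log2) of the members of 6 gene lists in M. galloprovincialis (blue) and M. trossulus (orange), with a black bar at each median. The proteasome medians lie at -0.31 and 0.13 and the ribosomal medians at 0.36 and 0.33.

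The second comparison gives the salinity effect within each species. In M. galloprovincialis the named targets with the largest falls beyond those above were variable region-containing chitin-binding protein 5 (MYC12650, log2 -2.34 ± 0.64, adjusted p = 0.0325), a candidate immune receptor of the gut and gill epithelia of invertebrates, and neuropeptide Y (MYC12701, log2 -1.49 ± 0.31, adjusted p = 0.00799), a signalling peptide. Tick legumain (MYC07203), a lysosomal protease, fell by 1.41 ± 0.32, syndecan binding protein (MYC01792) by 1.32 ± 0.37 and the DNA helicase Ruvbl1 (MYC08324) by 1.03 ± 0.29, with adjusted p of 0.012, 0.0355 and 0.0371. Higher levels were found for the chromatin remodelling factor SWI/SNF-related regulator of chromatin a5 (MYC11940, 1.13 ± 0.28), hairy G protein (MYC05812, 0.94 ± 0.26), the matrix protein thrombospondin 3 (MYC02772, 0.92 ± 0.26), CCR4-NOT transcription complex subunit 10-A (MYC05529, 0.70 ± 0.17) and mitochondrial intermediate peptidase (MYC03255, 0.66 ± 0.17), with adjusted p of 0.0189, 0.0334, 0.0325, 0.0195 and 0.0289 (n = 6 mussels per group). None of these 10 targets passed the test of the difference between species. With scan day as a block 6 of them missed the threshold, namely variable region-containing chitin-binding protein 5 (-2.15, adjusted p = 0.0952), syndecan binding protein (-1.12, 0.074), Ruvbl1 (-0.98, 0.0765), the chromatin regulator (0.99, 0.0511), hairy G protein (0.91, 0.0765) and the peptidase (0.55, 0.0765).

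The lists of the proteasome, ubiquitin conjugation and ligases, immediate early factors and translation factors shifted lower in M. galloprovincialis. The proteasome list, the complex that degrades ubiquitin-tagged proteins, had a median of -0.31 (adjusted p = 0.0033; adjusted p = 0.31 with an estimated correlation), with 1 of 15 members called lower, the 26S subunit non-ATPase 2 (MYC04852, log2 -0.47, adjusted p = 0.0219), and 5 lower adjusted over the list alone. Ubiquitin conjugation and ligases had a median of -0.33 (2 of 20 called lower, 6 lower and 1 higher adjusted over the list alone, adjusted p = 0.0033; adjusted p = 0.31 with an estimated correlation). Immediate early factors had a median of -0.30 (3 of 20 called lower, 7 adjusted over the list alone, adjusted p = 0.0033; adjusted p = 0.31 with an estimated correlation). Translation factors had one of -0.18 (3 of 27 called lower, 6 adjusted over the list alone, adjusted p = 0.041; adjusted p = 0.32 with an estimated correlation), and ribosomal proteins one of 0.36 (0 of 7 called, 1 higher adjusted over the list alone, adjusted p = 0.041; adjusted p = 0.32 with an estimated correlation). Chaperones of the cytosol were not called as a list (adjusted p = 0.053), but 4 of 37 members fell, among them subunit 5 (MYC00320, log2 -0.76, adjusted p = 0.013) and subunit delta (MYC03008, log2 -0.79, adjusted p = 0.012) of the TCP1 chaperonin, which folds actin and tubulin. Single members of other lists that fell were carbonic anhydrase (MYC07126, -0.60) and vacuolar ATP synthase subunit B (MYC01554, -0.70), which act in acid-base and ion transport, proliferating cell nuclear antigen (MYC07419, -0.83), the actin-severing protein gelsolin (MYC00051, -0.77), alpha-aminoadipic semialdehyde dehydrogenase (MYC05506, -0.99) and phosphoenolpyruvate carboxykinase (MYC04509, -1.01), with adjusted p of 0.0363, 0.0289, 0.0115, 0.0329, 0.0212 and 0.0103. The single list members named in this paragraph were followed under the alternatives only for the salinity effect over both species. Whether their calls in M. galloprovincialis alone would hold there was not checked.

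In M. galloprovincialis 149 targets were called, 50 higher and 99 lower, 62 of them annotated (750 with an unadjusted p under 0.05). Their direction was the same within scan day 2 in 148 of 149 cases, within day 3 in 149 and within day 5 in 133, and with scan day as a block 78 targets were called. The list medians on days 2, 3 and 5 were -0.46, -0.30 and 0.23 for the proteasome (adjusted p = 0.0071 with the block), -0.26, -0.23 and -0.11 for the ubiquitin list, -0.34, -0.13 and -0.15 for immediate early factors, -0.09, -0.14 and -0.15 for translation factors (adjusted p = 0.055 with the block) and 0.00, 0.69 and 0.30 for ribosomal proteins (adjusted p = 0.014 with the block). The count rested on single arrays, being 55 without replicate 1 at 850 mOsm/kg and 250 without replicate 5, and a fit of the compared arrays alone called 12. Replicate 1 was scanned on day 1, when no 4 h control of its species was scanned. Apart from the estimated correlation, the call of the translation list ended under 9 alternatives and that of the ribosomal list under 6, among them that without saturated probes (adjusted p = 0.061 and 0.099), the ubiquitin and immediate early lists missed the threshold with the authors' value table (adjusted p = 0.076 each), and the proteasome did with scale normalisation (0.052).

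In M. trossulus 24 targets were called, 3 higher and 21 lower (329 with an unadjusted p under 0.05), and 6 of them were annotated. These were C/EBP (MYC06119, log2 -1.65 ± 0.25, adjusted p = 0.00016), BIRC3 (MYC12204, -1.43 ± 0.34, adjusted p = 0.0356), pannexin 2 (MYC02781, -1.31 ± 0.31, adjusted p = 0.0356), the amino acid transporter (MYC01780, -1.22 ± 0.16, adjusted p = 6.4e-06), bone morphogenetic protein 2/4 (MYC13283, -0.91 ± 0.21, adjusted p = 0.0356) and LPS-induced TNF-alpha factor (MYC02904, -0.995 ± 0.25, adjusted p = 0.0496). Of the lists, the proteasome (median 0.13, 0 of 15 members called, 0 adjusted over the list alone) and ribosomal proteins (median 0.33, 0 of 7 called, 0 adjusted over the list alone) shifted higher, each with adjusted p = 0.0091, and immediate early factors shifted lower (median -0.04, mean -0.26, 1 of 20 called lower, 5 adjusted over the list alone, adjusted p = 0.012). Each had an adjusted p = 0.44 with an estimated correlation. On scan days 2, 3 and 5 these medians were 0.21, 0.08 and 0.02 for the proteasome, 0.05, 0.65 and 0.04 for ribosomal proteins and 0.06, -0.44 and -0.06 for immediate early factors, whose median was 0.08 without loess, where that of all targets was 0.103 and the list was still called lower (adjusted p = 0.016). With scan day as a block the proteasome and ribosomal lists had adjusted p of 0.12 and 0.058, and 22 targets were called. Direction within scan days 2, 3 and 5 was the same for 24, 24 and 21 of the 24 targets. The count fell to 11 without the 3 arrays of high background and to 5 without replicate 5 of the 4 h control, and no list was called with scale normalisation. The immediate early list was not called either without a filter on dim probes (adjusted p = 0.29), with the authors' value table (0.20) or without those 3 arrays (0.10), nor were ribosomal proteins with the processed signals (0.06).

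Across all 3524 targets the salinity effect had the same direction in both species in 54.7% of targets, with a Pearson's r of 0.19 across targets, which are not independent replicates. Of the targets called lower, 6 were shared by the 99 of M. galloprovincialis and the 21 of M. trossulus, where independent lists would share 0.59, and of those called higher none was shared.

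**Figure D3:**
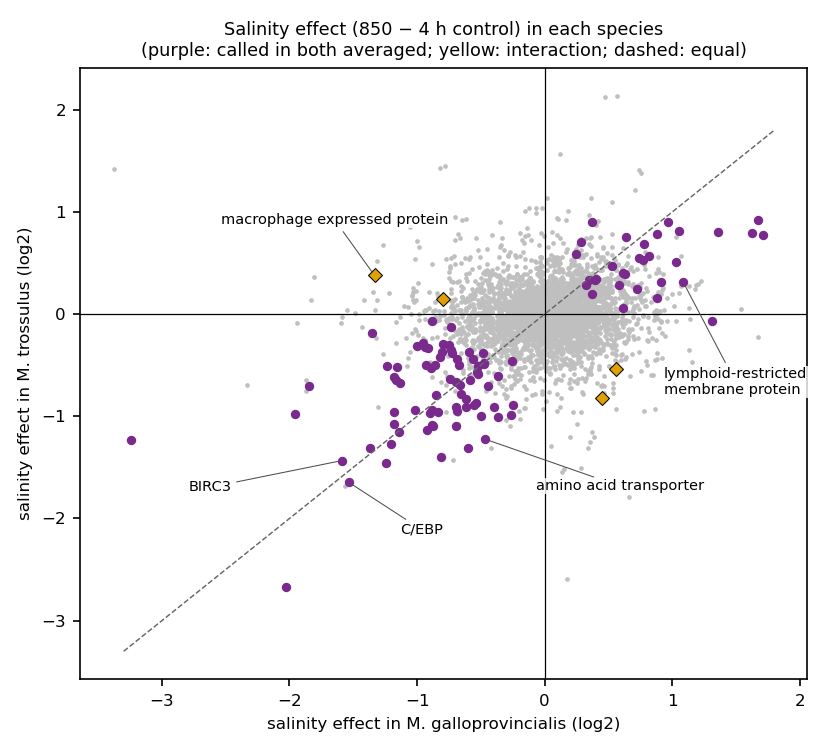
Salinity effect (log2) of 3524 targets in M. galloprovincialis against M. trossulus, with the 105 targets called over both species in purple and the 4 targets called for the interaction in yellow. Of the 105 targets, 104 have the same direction in both species, which selection by the average of the species favours. Of the targets called in M. galloprovincialis, 91 of 149 had the same direction in M. trossulus. Of those called in M. trossulus, 19 of 24 had the same direction in M. galloprovincialis.

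The third comparison tests whether the response to low salinity differed between the species. Macrophage expressed protein (MYC13618), a pore-forming protein of the immune defence, was the 1 annotated target that passed. It fell in M. galloprovincialis (log2 -1.33 ± 0.22, adjusted p = 0.000889) and was at 0.38 ± 0.22 in M. trossulus (adjusted p = 0.641), a difference of -1.71 (adjusted p = 0.0142), which was -2.17, -0.55 and -1.61 within scan days 2, 3 and 5 and missed the threshold with scan day as a block (-1.49, adjusted p = 0.127). Macrophage expressed protein had 1 kept probe. At low salinity it was well above background on 4 of 6 arrays of M. galloprovincialis and 5 of 6 of M. trossulus. The sizes of its fall and of the difference are therefore fitted values. Multiple banded antigen (MYC04837), CDC5 cell division cycle 5-like (MYC11982), cytochrome P450 2U1 (MYC12116) and phosphoenolpyruvate carboxykinase (MYC04509) came next and did not pass, with adjusted p of 0.0916, 0.0969, 0.0969 and 0.0969. The other 3 targets that passed have no annotation and were named after their values were seen. They were MYC03661 (log2 0.45 in M. galloprovincialis and -0.82 in M. trossulus), MYC01418 (-0.80 and 0.15) and MYC02756 (0.56 and -0.54).

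The proteasome list was lower in M. galloprovincialis relative to M. trossulus, with 14 of its 15 members below 0 and a median difference of -0.43 (0 of 15 members called, 4 lower adjusted over the list alone, adjusted p = 1.9e-06; adjusted p = 0.084 with an estimated correlation). Heat shock proteins and cytosolic chaperones had a median difference of -0.23 (0 of 37 called, 3 lower adjusted over the list alone, adjusted p = 0.017; adjusted p = 0.32 with an estimated correlation). Within scan days 2, 3 and 5 the medians were -0.68, -0.39 and 0.05 for the proteasome (adjusted p = 6.8e-05 with the block) and -0.73, -0.05 and -0.10 for the chaperones, whose call ended with the authors' value table (adjusted p = 0.22) and with scale normalisation (0.09). By limma 4 targets were called, 2 in each direction, and 425 had an unadjusted p under 0.05. No target was called with scan day as a block, in the fit of the compared arrays alone or with the authors' value table, and 19 were called without replicate 5 of M. galloprovincialis at 850 mOsm/kg. The unmatched arrays of scan days 1 and 4 carry any difference between days into this contrast, unless scan day is a block.

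The fourth comparison sets the 4 h control against the start at unchanged salinity, the background of the salinity effect. Transfer to a tank, corked valves and the hour of sampling changed together and cannot be separated. Eukaryotic initiation factor 4A (MYC05671), an RNA helicase of translation initiation, rose by 2.96 ± 0.15 on the log2 scale over both species (adjusted p = 9.6e-17, n = 6 mussels per group and species). Glutamine synthetase (MYC13120), which makes glutamine from ammonia and glutamate, rose by 2.93 ± 0.28, GTP-binding protein SB128 (MYC02740) by 2.93 ± 0.21, variable region-containing chitin-binding protein 5 (MYC12650) by 2.82 ± 0.46, an H+-ATPase V-type subunit (MYC05404) by 2.59 ± 0.21 and Kruppel-like factor (MYC06168) by 2.57 ± 0.25. BIRC3 (MYC12204) was not well above background on any zero-time array and was at least 7.62-fold higher after 4 h in M. galloprovincialis and at least 4.89-fold higher in M. trossulus (adjusted p = 1.3e-11 over both species). Pannexin 2 (MYC02781) was at least 6.73-fold higher in M. trossulus, and pannexin 3 (MYC08299) at least 4.74-fold higher in M. galloprovincialis and at least 3.31-fold in M. trossulus. C/EBP (MYC06119) rose by 2.11 ± 0.18 and c-Jun (MYC06621) by 1.09 ± 0.22.

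Other named targets fell over 4 h. Rhamnose-binding lectin (MYC02855) fell by 2.29 ± 0.63 on the log2 scale (adjusted p = 0.00267), FCNB protein (MYC07290), named after a ficolin, by 2.07 ± 0.58 (adjusted p = 0.00317), precerebellin-like protein (MYC10999) by 1.83 ± 0.45 and macrophage galactose-type C-type lectin 2 (MYC13721) by 1.28 ± 0.50 (adjusted p = 0.0291). The last of these and alpha2-fucosyltransferase (MYC04912, -1.35, adjusted p = 0.0189) missed the threshold with scan day as a block (adjusted p of 0.236 and 0.248). The ETS-family transcription factor (MYC00286) fell by 1.65 ± 0.23, Rab3 GTPase-activating protein catalytic subunit (MYC02606) by 1.37 ± 0.22 and a zinc finger protein (MYC00869) by 1.24 ± 0.15.

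Immediate early transcription factors and stress signalling was the 1 list called over time, with 12 of 20 members called higher and 3 lower, 12 and 4 adjusted over the list alone, and a median of 0.70 (adjusted p = 0.0063; adjusted p = 0.51 with an estimated correlation; median of 0.67 within scan day 5). Of the lists not called, cilia and axoneme genes had 17 of 27 members called higher and 3 lower (17 and 4 adjusted over the list alone, adjusted p = 0.066), and hemocyte and immune genes had 7 of 39 higher and 11 lower (7 and 10 adjusted over the list alone, adjusted p = 0.38). By limma 2001 of 3524 targets were called over both species, 1062 higher and 939 lower, 784 of them annotated. In M. galloprovincialis 1596 targets were called (870 higher, 726 lower) and in M. trossulus 1250 (729 higher, 521 lower), and 81.0% of all targets had the same direction in both species. Within scan day 5, with 4 zero-time arrays and 1 array of the 4 h control per species, 1964 of 1998 targets had the same direction, as did 1562 of 1596 in M. galloprovincialis (1557 of 1595 within day 4) and 1217 of 1250 in M. trossulus. With scan day as a block 1554, 1372 and 985 targets were called.

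The time effect differed between the species in 18 targets (8 higher and 10 lower in M. galloprovincialis relative to M. trossulus, 460 with an unadjusted p under 0.05). The annotated ones, apart from the amino acid transporter, lie outside the rule for named genes and were named after their values were seen. HSP70 (MYC01479), an inducible chaperone, rose by 2.37 in M. galloprovincialis and by 0.89 in M. trossulus (difference 1.48, adjusted p = 0.013). Dynein axonemal heavy chain 7 (MYC02319), a motor of ciliary beating, had log2 changes of -0.10 and 1.69 (adjusted p = 0.0083), and the amino acid transporter (MYC01780) rose by 1.40 in M. trossulus, with 3 of 6 zero-time arrays well above background, and was at least 1.32-fold higher in M. galloprovincialis, where none was, so the size of the difference was not measured (adjusted p = 0.045). ATP-dependent transporter (MYC07371) had values of 0.41 and -0.66, nucleotide-binding protein 2 (MYC06520) of 1.15 and -0.70, and a second transcription elongation factor B polypeptide 3 binding protein 1 (MYC04227) of -1.04 and -0.29. Within scan day 5 the difference had the same direction in 18 of 18 targets, and with scan day as a block 12 targets were called.

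The salinity effect ran against the time effect in most called targets. Of the 105 targets called for salinity over both species, 94 were also called for time in the opposite direction and 0 in the same direction, and 75 had a level at 850 mOsm/kg between those of both controls, 61 of the 74 called lower but 14 of the 31 called higher. Signs were opposite in 98.1% of the 105 targets. Simulated targets without any effect had opposite signs in 66.7%, because both effects contain the 4 h control arrays. The simulated targets were not selected by call, and selection for a large salinity effect can itself raise the share of opposite signs. These shares therefore do not measure an excess. C/EBP, BIRC3, pannexin 2 and c-Jun were among the targets higher after 4 h in the tank and lower at 850 mOsm/kg, and the ETS-family transcription factor, the potassium channel and 40S ribosomal protein S6 among the reverse. Across targets, which are not independent replicates, Pearson's r between them was -0.60 in M. galloprovincialis and -0.48 in M. trossulus, and with the 4 h control arrays divided between the effects its median was -0.40 and -0.24.

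**Figure D4:**
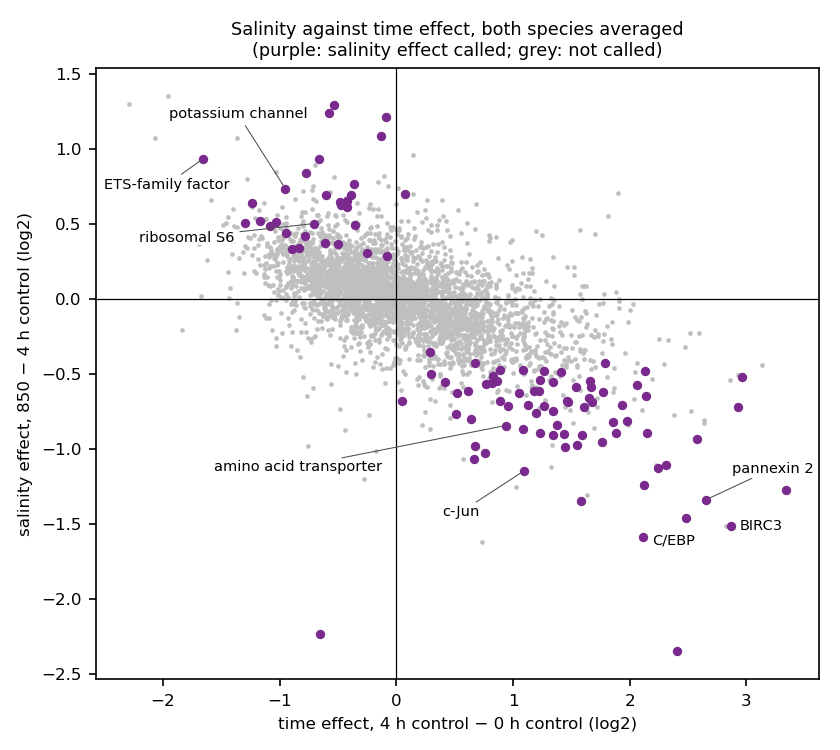
Salinity effect against time effect (log2, averaged over both species) of 3524 targets, with the 105 targets called for salinity in purple. Of these 105 targets, 103 (98.1%) have opposite signs. Both axes share the 4 h control arrays, which gave opposite signs in 66.7% of simulated unchanged targets. The simulated targets were not selected by call, so these shares do not measure an excess.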

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

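The tests of the 4 h controls shared by both effects, in each species and jointly, and the tests without the 3 high-background arrays, in each species and for the species difference, were chosen only after the result was seen, and those in each species were divided after both slopes were known.

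Single arrays stood far from the other 5 of their group, with a gap to the nearest array, over the range of the group, above Dixon's 95% critical value. Chance gives this in about 1 in 20 groups. It occurred in 9 of 36 groups for 6 measures of the arrays, which are not independent of each other. In M. galloprovincialis at 850 mOsm/kg, replicate 2 had a median red signal of 176.0 (the others 57.6 to 65.7, gap over range 0.931), the median green signal stood out too (153.2, 0.815), as did the share of probes above background in green (48.5%, 0.881). Replicate 4 of M. trossulus at 850 mOsm/kg had a median green signal of 365.8 (0.844). In zero-time controls, replicate 5 of M. galloprovincialis had a median red signal of 64.7 (0.653), and replicate 1 of M. trossulus had one of 78.7 (0.830) and 34.5% of probes above background in green (0.630). In 4 h controls, replicate 1 of M. galloprovincialis had an SD of log2 ratios of 0.747 (the others 0.865 to 0.889, 0.831) and replicate 1 of M. trossulus had 3.05% outlier spots (0.703).

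For the 69 named targets the same gap occurred in 28 of 414 groups, where chance would give 20.7, and no array had more than 2. In M. galloprovincialis at 850 mOsm/kg these were 40S ribosomal protein S6 (replicate 4, gap over range 0.875), warts (replicate 3, 0.736), the amino acid transporter (replicate 4, 0.667) and the 26S proteasome subunit (replicate 1, 0.631). In its 4 h control they were pannexin 2 (replicate 2, 0.765), c-Jun (replicate 5, 0.706), LPS-induced TNF-alpha factor (replicate 3, 0.642), GTP-binding protein SB128 (replicate 6, 0.639), Tick legumain (replicate 5, 0.700) and gelsolin (replicate 3, 0.760). In its zero-time control they were transcription elongation factor B polypeptide 3 binding protein 1 (replicate 6, 0.655), Kruppel-like factor (replicate 2, 0.630), immediate early response 5-like (replicate 2, 0.690), rhamnose-binding lectin (replicate 3, 0.678), alpha-aminoadipic semialdehyde dehydrogenase (replicate 6, 0.775) and myosin light chain kinase (replicate 3, 0.649). In M. trossulus at 850 mOsm/kg they were the elongation factor binding protein (replicate 5, 0.761), ceramide kinase (replicate 5, 0.766), the chromatin regulator a5 (replicate 2, 0.7498), neuropeptide Y (replicate 3, 0.857) and the 26S proteasome subunit (replicate 6, 0.677). In its 4 h control they were cysteinyl leukotriene receptor 1 (replicate 2, 0.892), the H+-ATPase V-type subunit (replicate 4, 0.716), FCNB protein (replicate 3, 0.831) and alpha-glucosidase-like protein (replicate 4, 0.677), and in its zero-time control pannexin 2 (replicate 5, 0.709), CCR4-NOT subunit 10-A (replicate 3, 0.694) and LPS-induced TNF-alpha factor (replicate 6, 0.836).

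The salinity effect was called as different between the species (M. galloprovincialis minus M. trossulus, log2) in macrophage expressed protein (MYC13618, fitted value -1.71), MYC03661 (1.26), MYC01418 (-0.95) and MYC02756 (1.09). The lists called were the proteasome (median -0.43) and heat shock proteins and cytosolic chaperones (-0.23). With scan day as a block 0 targets were called, and 6 of 100 splits of the arrays gave at least as many calls. With an estimated correlation 0 lists were called (camera adjusted p of 0.084 or more). The time effect differed in the amino acid transporter (MYC01780, fitted value -0.92, of unmeasured size since the target was not well above background on any zero-time array of M. galloprovincialis), HSP70 (MYC01479, 1.48), dynein axonemal heavy chain 7 (MYC02319, -1.79), ATP-dependent transporter (MYC07371, 1.07), nucleotide-binding protein 2 (MYC06520, 1.85) and transcription elongation factor B polypeptide 3 binding protein 1 (MYC04227, -0.75). It also differed in the targets without annotation MYC08862 (-1.32), MYC03328 (-1.102), MYC04153 (1.22), MYC04519 (-1.204), MPC01629 (2.10), MYC10909 (-1.13), MYC07484 (-1.29), MYC00260 (-1.01), MYC07521 (1.58), MYC07410 (-1.94), MYC02512 (fitted value 1.55, with the same limit as the amino acid transporter) and MYC06983 (2.76).

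The first pattern is the time effect, with 2001 targets called. A difference between scan days as its whole cause was argued against, since within scan day 5 the time effect kept 0.798 or more of its size between days in each species. GC content of the probes was argued against as well, with a Spearman's rho of 0.0737 between GC content and time effect over targets. The candidate biological causes, transfer to a tank, corked valves and the hour of sampling, changed together in the design and were not tested apart.

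The second pattern is that the salinity effect ran against the time effect, which the shared 4 h control arrays alone could produce. Set against the time effect of the other species, which shares no array with it, the salinity effect had a slope of -0.181 in M. galloprovincialis (exact permutation p = 0.0108 over 924 splits), which argued against shared arrays as the whole cause there, and -0.128 in M. trossulus (p = 0.173), where they and a lesser change over time cannot be told apart because other splits gave slopes as steep. Jointly, the mean slope was -0.154 (permutation p = 0.00521 over 853776 splits, with the time effects held fixed). Each slope contains the 4 h control arrays of both species, so the slopes are not independent and this joint p is not exact. Of the targets called for salinity, which are not independent of each other, 124 of 149 in M. galloprovincialis and 22 of 24 in M. trossulus ran against the time effect of the other species (61.9% and 59.8% of all targets). Without the 3 high-background arrays the slope kept 0.988 of its size in M. galloprovincialis (exact permutation p = 0.0173), which argued against these arrays there, and 0.718 in M. trossulus (exact permutation p = 0.462), where 4 arrays were left at 850 mOsm/kg and these arrays cannot be told apart from a change with salinity, and within scan days 2 and 3 all slopes were negative (-0.0993 and -0.161 in M. galloprovincialis, -0.0344 and -0.358 in M. trossulus) but, with 2 arrays per group and day, varied too much to exclude the scan day. In M. galloprovincialis low salinity may have weakened the change seen over 4 h, with the scan day and the tank still open. However, over both species only 14 of 31 targets called higher, against 61 of 74 called lower, lay between both controls.

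The third pattern is that 149 targets were called for salinity in M. galloprovincialis and 24 in M. trossulus, which became 35 and 18 with the processed signals, 12 and 6 with only the arrays compared, 78 and 22 with scan day as a block, 55 and 26 without replicate 1 of M. galloprovincialis at 850 mOsm/kg and, the other way, 98 and 4 without loess. Noisier arrays of M. trossulus were argued against, with a ratio of median residual SDs of 1.04 (M. trossulus over M. galloprovincialis). Without the 3 high-background arrays 99 and 11 targets were called, but this left fewer arrays of M. trossulus, and with 4 arrays at 850 mOsm/kg in each species the ratio of calls ranged from 1.92 without replicate 1 of M. galloprovincialis to 22.6 without its replicate 5 (6.21 with all arrays), so these arrays cannot be told apart from a species difference. A weaker response of the probes to M. trossulus transcripts cannot be told apart from a weaker response of the mussels, since the noise-corrected SD of its time effects was 0.869 of that in M. galloprovincialis (0.590 for salinity) and no shared standard was measured. A species difference may add to it, but few single targets passed the test of the difference.

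Other splits of the arrays within species, 100 with the real one, tested chance as the source of each count. They did not keep scan days or tanks together, so they separate neither the scan day nor the tank from the groups. Chance differences between single mussels were argued against as the whole source for salinity in both species (105 targets called, 22 at most in any other split) and in M. galloprovincialis (149 and 12). In each, 1 of the 100 splits gave as many, the real one, which is the lowest share these splits could give. In M. trossulus (24 and 22) only the real split gave as many too, but the margin is too narrow to exclude chance. The split with 22 mixed the groups of M. trossulus evenly (3 of 6 arrays). The real count there was 22 with scan day as a block and 5 to 7 without each of 4 single arrays. Chance cannot be excluded for the species difference in salinity (4 called, 8 in the highest other split, 6 splits with at least as many). For time, chance differences between single mussels were argued against in both species (2001 and 1239), in M. galloprovincialis (1596 and 558) and in M. trossulus (1250 and 241), each with 1 split giving as many, the real one. For the species difference in time 4 splits gave at least the real 18, a share under 0.05, but the highest other gave 1117. That split kept 5 of 6 arrays of a group of M. galloprovincialis together and 1 of 6 in M. trossulus, so it nearly mirrored the groups of 1 species, and the structure of the samples, a time effect in both species, produced its calls.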

How the results depend on the processing

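The alternatives without the 3 high-background arrays, with the background that Feature Extraction used, with scale normalisation between arrays, and, for gene lists alone, without saturated probes were chosen after seeing the data. Over the alternatives for single named targets, 1087 values kept their direction and side of the threshold, 258 kept their direction but missed the threshold, 8 passed it, and 60 reversed. Many of the 1087 belong to effects that were not called and stayed so. Examples over both species are proliferating cell nuclear antigen (19 of 19 alternatives) and gelsolin (18 of 19). The 1087 therefore do not measure how stable the calls were. The 1087 include values that could hardly change, namely 80 with Aquantile normalisation, 48 with called interactions left out and 79 with only M. californianus probes. Scan day as a block could hardly move the salinity effects over both species either. The counts of the time effect in both species and in each species changed by more than 1.5 times only with the stricter filter and with each probe alone. Background from Feature Extraction gave 114 targets for salinity in both species, 158 in M. galloprovincialis and 21 in M. trossulus. Leaving out targets with a called interaction left 105, and Aquantile normalisation leaves log ratios as they are and tested nothing. The slide as a block was not run, since the files give no slide. Signal over background limits the tests, since 6193 of 44570 probes passed the filter and 3739 the stricter filter. The median of all targets moved by more than 0.1 (log2) in 1 case, from -0.0022 to 0.103 for salinity in M. trossulus without loess, and list medians there are read relative to it. Except where said, the cause was not tested.

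For salinity in both species 105 targets were called, and the count was 54 with the Agilent processed signals, 29 (1 higher, 28 lower) with scale normalisation, 63 with the stricter filter (fewer targets tested), 193 with each probe alone (more tests), 51 with the authors' value table, 19 with both controls pooled, 1654 with the zero-time control, 45 with the authors' 2-way analysis of variance, 48 with only the arrays compared (fewer arrays), 68 with array weights and 59 without the 3 high-background arrays. Without loess 57 of 95 were higher and 38 lower. For M. galloprovincialis 149 targets became 35 with the processed signals (14 higher, 21 lower), 98 without loess (45 higher, 53 lower), 36 with scale normalisation (4 higher, 32 lower), 84 with the stricter filter, 316 with each probe alone, 52 with the authors' value table (12 higher, 40 lower), 2 with both controls pooled, 1080 with the zero-time control, 12 with only the arrays compared, 78 with scan day as a block and 99 without the 3 high-background arrays. For M. trossulus 24 became 4 without loess (all lower), 3 with scale normalisation (all lower), 6 without a filter on dim probes, 42 with each probe alone, 4 with the authors' value table (1 higher, 3 lower), 0 with both controls pooled, 970 with the zero-time control, 6 with only the arrays compared, 5 with array weights and 11 without the 3 high-background arrays.

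For the species difference in salinity 4 targets became 0 with the processed signals, the stricter filter, the authors' value table, both controls pooled, the 2-way analysis of variance, only the arrays compared and scan day as a block. They became 1 without background correction, without loess, with scale normalisation, with array weights and without the 3 high-background arrays, 2 without a filter and with the zero-time control, and 7 with replicate number as a block. For time, 2001 targets became 1299 with the stricter filter and 3498 with each probe alone, 1596 in M. galloprovincialis became 1015 and 2769, and 1250 in M. trossulus became 822 and 2155. Without loess the time effect had 993 higher and 423 lower in M. galloprovincialis and 615 and 632 in M. trossulus. For the species difference in time 18 became 29 with the processed signals, 4 with scale normalisation, 77 without a filter, 61 with each probe alone, 44 with the authors' value table (31 higher, 13 lower), 44 with the 2-way analysis of variance, 39 with only the arrays compared and 40 with array weights, and without loess 18 of 19 were higher, as were 14 of 24 both without background correction and with the Feature Extraction background.

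With an estimated correlation 0 gene lists were called in any comparison. The 3 lists of salinity in both species became 5 without a filter. The 5 of M. galloprovincialis became 3 with the processed signals, 2 with the authors' value table, 9 without a filter, and 3 each with replicate number as a block, without the 3 high-background arrays and without saturated probes. The 3 of M. trossulus became 0 with scale normalisation and 1 with scan day as a block. The 2 of the species difference became 1 with the authors' value table, 4 with the stricter filter and 1 with scale normalisation. The 1 list of time became 3 without loess, with the authors' value table and with the stricter filter, 10 without a filter and 2 with replicate number as a block.

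Leaving out 1 array at a time gave 67 to 173 targets for salinity in both species, 55 to 250 in M. galloprovincialis, 5 to 26 in M. trossulus and 1 to 19 for their difference, and for time 1914 to 2014, 1470 to 1639, 1123 to 1275 and 8 to 24. In both species the count was 166 without replicate 5 of M. galloprovincialis at 850 mOsm/kg, and 173 and 67 without replicates 1 and 4 of the M. trossulus 4 h control. In M. galloprovincialis it was 55, 98 and 250 without replicates 1, 2 and 5 at 850 mOsm/kg and 96 without replicate 5 of the 4 h control. In M. trossulus it was 15, 12, 14 and 6 without replicates 2, 3, 4 and 6 at 850 mOsm/kg, and 12, 7, 6 and 5 without replicates 1, 2, 4 and 5 of the 4 h control. Of these, replicate 6 at 850 mOsm/kg and replicate 1 of the 4 h control had no array of the compared group on their scan day. For their difference it was 19 without replicate 5 of M. galloprovincialis at 850 mOsm/kg and 7 without replicate 3 of the M. trossulus 4 h control. It was 1 without replicates 2 and 4 of M. galloprovincialis at 850 mOsm/kg, 4 and 5 of its 4 h control and 5 of its zero-time control, and without replicates 3, 4 and 6 of M. trossulus at 850 mOsm/kg, 1 and 6 of its 4 h control and 2 and 5 of its zero-time control. It was 2 without replicates 3 and 6 of the 4 h control and 1 of the zero-time control of M. galloprovincialis, and without replicates 1 and 2 at 850 mOsm/kg and 2 and 5 of the 4 h control of M. trossulus. For the difference in time it was 11 without replicates 3, 4 and 5 and 10 without replicate 6 of the M. galloprovincialis 4 h control, and 10, 11, 8 and 11 without replicates 1, 3, 5 and 6 of its zero-time control. In M. trossulus it was 11 without replicates 1 and 3 of the 4 h control and 8 without replicate 1 of the zero-time control. Arrays of the same number had correlations of -0.08 to 0.15 across groups of a species after removal of group means, which gave no sign that numbers pair mussels. In the 850 mOsm/kg and 4 h control groups replicates 2 and 3 were scanned on day 2 and replicates 4 and 5 on day 3, so there the number carries the scan day.

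With the zero-time control the contrast also contains the time effect, which accounts by construction for 43 reversed salinity effects. In both species these were ETS-family transcription factor (MYC00286, -0.72), Potassium channel (MYC00516, -0.22), 40S ribosomal protein S6 (MYC00152, -0.20), Complement component 1 Q subcomponent-binding protein (MYC02037, -0.36), CCAAT/enhancer binding protein (MYC06119, 0.52), baculoviral IAP repeat-containing 3 (MYC12204, 1.35), Pannexin 2 (MYC02781, 1.31), ubiquitin-protein ligase-like (MYC03819, 0.88), Cysteinyl leukotriene receptor 1 (MYC05297, 0.57), Kruppel-like factor (MYC06168, 1.64), immediate early response 5-like (MYC07287, 0.44), Pannexin 3 (MYC08299, 1.26), Tumor necrosis factor receptor superfamily member 19 (MYC02394, 0.22), Amino acid transporter (MYC01780, 0.0916), LPS-induced TNF-alpha factor (MYC02904, 0.60), Sterile alpha motif domain-containing protein 7 (MYC05755, 0.89), GTP-binding protein SB128 (MYC02740, 2.20), Chaperonin containing TCP1, subunit 5 (MYC00320, 0.36), T-complex protein 1 subunit delta (MYC03008, 0.76), Taurine transporter (MYC10085, 0.27), Carbonic anhydrase (MYC07126, 0.19), Vacuolar ATP synthase subunit B (MYC01554, 0.81), the 26S proteasome subunit (MYC04852, 0.0415), Ubiquitin-conjugating enzyme E2-17 kDa (MYC06364, 0.24), Alpha-aminoadipic semialdehyde dehydrogenase (MYC05506, 0.51), Dual specificity protein phosphatase 3 (MYC12306, 0.32), Eukaryotic initiation factor 4A (MYC05671, 2.44), Phosphoenolpyruvate carboxykinase (MYC04509, 0.74), Intraflagellar transport protein 52 (MYC10132, 0.25), Gelsolin (MYC00051, 0.13), Macrophage expressed protein (MYC13618, 0.70), myosin light chain kinase (MYC09425, 0.95), Pancreatic lipase (MYC06633, -0.45), Angiotensin-converting enzyme (MYC04213, -0.11), Alpha-glucosidase-like protein (MYC01260, -0.37), Chitin synthase (MYC09846, 0.75) and Tick legumain (MYC07203, 0.79). In M. galloprovincialis they were Hairy G protein (MYC05812, -0.82), thrombospondin 3 (MYC02772, -0.19), Variable region-containing chitin-binding protein 5 (MYC12650, 1.59), Neuropeptide Y (MYC12701, 1.38), Tick legumain (MYC07203, 0.58) and Syndecan binding protein (MYC01792, 1.41). In 1 or both species baculoviral IAP repeat-containing 3, Pannexins 2 and 3, Tumor necrosis factor receptor superfamily member 19, the amino acid and taurine transporters, TCP1 subunit 5, Vacuolar ATP synthase subunit B and Macrophage expressed protein were not well above background on any zero-time array, so their values here and with pooled controls are fitted values that do not measure a size.

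With both controls pooled, the contrast contains part of the time effect, and 16 salinity effects reversed. These were Kruppel-like factor (MYC06168, 0.42), Pannexin 3 (MYC08299, 0.18), Sterile alpha motif domain-containing protein 7 (MYC05755, 0.081), GTP-binding protein SB128 (MYC02740, 0.74), T-complex protein 1 subunit delta (MYC03008, 0.19), Taurine transporter (MYC10085, 0.0829), Vacuolar ATP synthase subunit B (MYC01554, 0.27), Alpha-aminoadipic semialdehyde dehydrogenase (MYC05506, 0.00981), Eukaryotic initiation factor 4A (MYC05671, 0.96), Phosphoenolpyruvate carboxykinase (MYC04509, 0.18), Macrophage expressed protein (MYC13618, 0.11), myosin light chain kinase (MYC09425, 0.18), Alpha-glucosidase-like protein (MYC01260, -0.14), Chitin synthase (MYC09846, 0.00347) and Tick legumain (MYC07203, 0.0768), and in M. galloprovincialis Syndecan binding protein (MYC01792, 0.0455). Without a filter on dim probes Alpha-glucosidase-like protein (MYC01260, -0.00514) reversed. The other named values that missed the threshold did so for 33 effects with both controls pooled, 32 with scale normalisation, 32 with the authors' value table, 26 with only the arrays compared, 22 with the processed signals, 20 with the 2-way analysis of variance, 16 without a filter, 16 without the 3 high-background arrays, 15 without loess, 11 with the zero-time control, 11 with array weights, 9 with scan day as a block, 5 with replicate number as a block, 4 with the stricter filter, 3 without background correction, 2 with the Feature Extraction background and 1 with only M. californianus probes. Called effects that kept their call in fewer than 1 of 2 alternatives were in both species Ceramide kinase, Complement component 1 Q subcomponent-binding protein, warts, Kruppel-like factor, GTP-binding protein SB128, Heat shock protein 25, Ubiquitin-conjugating enzyme E2-17 kDa, Dual specificity protein phosphatase 3 and Eukaryotic initiation factor 4A, and in M. galloprovincialis Hairy G protein, Variable region-containing chitin-binding protein 5, Syndecan binding protein and Ruvbl1. The alternatives counted include those that could hardly change a value. Without them further calls, such as 40S ribosomal protein S6 (10 of 19), Pannexin 3 (10 of 18) and myosin light chain kinase (10 of 19), would fall to about this line or below it.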

Other observations

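The test of probe pairs in this part was chosen before its result was seen.

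Over 4 h in the tank, no other list passed the list test over both species, and 56.8% of all targets were called, so many called members do not mark a group. Translation factors had 14 of 27 members called higher and 4 lower (median 0.28, adjusted p = 0.10), ubiquitin conjugation and ligases 12 of 20 higher and 2 lower (median 0.54, adjusted p = 0.051), and lysosomal genes 7 of 16 higher and 0 lower (median 0.40, adjusted p = 0.19). Chaperones of the endoplasmic reticulum had 5 of 6 members called higher (median 0.57, adjusted p = 0.14) and ion pumps and acid-base enzymes 5 of 7 (median 0.51, adjusted p = 0.087). Ribosomal proteins had 4 of 7 called lower and 1 higher (median -0.69, adjusted p = 0.10) and the proteasome 7 of 15 lower and 3 higher (median -0.23, adjusted p = 0.19). Heat shock proteins and cytosolic chaperones had 15 of 37 called higher and 6 lower (adjusted p = 0.27), glycolysis 7 of 15 higher and 1 lower (adjusted p = 0.19) and antioxidant and detoxification genes 8 of 34 higher and 10 lower (adjusted p = 0.67). The last 3 groups and the lysosomal genes held no larger share of called members than all targets.

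No other list was called for salinity over both species. Of the 4 tested transporters of organic osmolytes, 1 was called for salinity, the amino acid transporter, and with a median of 0.01 the list mean was -0.11. Heat shock proteins had 1 of 37 members called lower (median 0.00, mean -0.07, adjusted p = 0.64), hemocyte and immune genes 1 of 39 higher (median 0.08, adjusted p = 0.97) and apoptosis genes 3 of 27 lower (median 0.01, mean -0.16, adjusted p = 0.27).

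A hypothesis was that mismatches between M. californianus probes and M. galloprovincialis transcripts lower the measured effect. For 301 pairs of probes for the same transcript, 1 designed on each species, the slope of the time effect of the M. californianus probes on that of the M. galloprovincialis probes was 0.856 in M. galloprovincialis (Pearson's r of 0.884 across pairs). Noise in the probe on the horizontal axis also lowers a slope, and the same slope was 0.907 in M. trossulus, so the slope cannot tell mismatch and noise apart. In M. galloprovincialis the SD of the time effect was 0.762 for the M. californianus probes and 0.787 for the paired M. galloprovincialis probes. The median difference in absolute size was 0.002. These values show no large lowering of the measured effect, but noise enters the SDs too.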
